A study of Mus musculus with 16 samples.

How the data were processed

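Polysome RNA of mouse kidney glomeruli was measured on 16 microarrays, 4 in each of 4 groups. RiboTag mice carry a form of Rpl22, a protein of the large ribosomal subunit, that gains an HA epitope where Cre recombinase acts. Antibody to the epitope then pulls down the ribosomes of the chosen cells with the mRNA on them. Here Cre was driven by Nphs1, the gene of the slit diaphragm protein nephrin, so the tagged ribosomes were those of podocytes, the epithelial cells that cover the glomerular capillaries. Per the labels, podocyte RNA came from polysomes precipitated with the antibody and glomerular RNA from polysomes that were not precipitated. NEP25 mice express human CD25 on podocytes, and LMB2 is an immunotoxin that binds CD25 and blocks protein synthesis through the elongation factor Eef2. Per the labels, LMB2 was given once into the tail vein at 0.625 ng per g of body weight to mice that carried both the tag and NEP25, and podocyte RNA was taken 4 or 7 days later. The series text describes the uninjured mice as carrying the tag alone, and all were on the C57BL/6N background. The labels do not say whether each array holds a separate animal, so every p-value measures the spread between samples.

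Per the file headers, each array was a 1-colour Agilent design read with Feature Extraction 11.5.1.1. The deposited files hold, for each spot, a processed intensity on a linear scale, already background-subtracted and detrended by that program, together with the raw median intensity of the spot and of its local background. The deposited files also hold flags for spots well above background, saturated spots and outlying spots. None of these values had been normalized between arrays. The authors' value table holds log2 values of 39430 probes. Each of its 16 columns was an exact shift of the log2 processed intensity of 1 array, and the column medians ran from -3.17 to -2.51. The normalization behind the shift is not stated. For 6 columns, replicates 1 to 3 of both normal groups, the matching array was another replicate of the same group, and no column matched another group. The scanner files' own names were used here, and group membership does not depend on the choice.

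Control spots and outlying spots were left out, and log2 values of spots of 1 probe were averaged, which gave 55681 probes. Each array held 59305 spots other than controls, and none was saturated. Between 49.3% and 57.5% of spots were well above background on an array, and the 75th percentile of the processed intensity ran from 227 to 415. The number of arrays limits the precision. Probe accessions were matched without versions to a RefSeq gene table of the mouse genome, which named 26576 probes with 1 symbol, 20141 genes in all, and left 29105 probes without a name. The log2 processed intensity minus the array's 75th percentile was the value tested. Probes were kept when well above background on all 4 arrays of at least 1 group, 19056 named probes after 106 probes missing on some array were set aside. A gene was represented by its kept probe with the highest mean over the 16 arrays, giving 14573 genes. Among called genes with several probes, all probes had the same sign in 94.5% for podocyte against glomerular RNA, 77.6% for day 4 against normal, 82.4% for day 7 against normal and 91.5% for day 7 against day 4.

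All 16 arrays entered 1 linear model with group as the only term (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 12 residual degrees of freedom), and arrays were read with Python 3.11.15. The 4 comparisons were podocyte against glomerular RNA of uninjured mice, day 4 against normal podocytes, day 7 against normal podocytes, and day 7 against day 4. A gene was called when limma's Benjamini-Hochberg adjusted p over the 14573 genes was under 0.05. Changes are given on the log2 scale with limma's standard error and n = 4 arrays per group. Where a gene was well above background on every array of 1 group and on none of the other, only a bound is given, "at least N-fold". That bound sets the bright group's mean against the mean, over the dim arrays, of the higher of the probe's own value and the lowest value of any probe well above background on that array.

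Lists of genes were fixed before the data were examined, as were the design, the rule for named genes and most of the alternatives. The 23 lists hold markers of podocytes, endothelial cells, mesangial and smooth muscle cells, parietal epithelial cells, proximal tubule, distal nephron, leukocytes and red blood cells, and genes of the glomerular basement membrane, the unfolded protein and integrated stress responses, p53 targets, immediate early genes, YAP and TEAD targets, cytokines and NF-kappaB targets, interferon-stimulated genes, injury-related matrix, proliferation, actin and adhesion, cell death, lysosome and autophagy, translation elongation, ribosomal proteins and oxidative phosphorylation. Cd68, Hbb-b1, Mx1 and Mx2 had no matching probe. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 23 lists of a comparison. Camera asks whether the genes of a list rank above or below the other genes. With the correlation estimated from the data instead, no list was called in any comparison, and that adjusted p stands beside each list's result.

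The named genes are, for each comparison, the 6 largest rises and the 6 largest falls among called genes changed at least 2-fold, with all 4 arrays of 1 group above all 4 of the other and every array well above background. Added to these are the 3 largest rises and 3 largest falls known only as bounds, up to 4 members of each list with the smallest adjusted p, and, in every comparison, Nphs1, Podxl, Wt1, Synpo, Rpl22 and Eef2. Clone identifiers were skipped, and the results of some genes this rule names are not given. A few members that went against their list are named too, chosen after their values were seen.

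All normal arrays lay on slide 1 and all LMB2 arrays on slide 2, and the slides were scanned apart. Podocyte against glomerular RNA and day 7 against day 4 are therefore comparisons within a slide, while each comparison of LMB2 with normal runs between slides, genotypes and treatments at once, and these cannot be told apart. On the LMB2 slide all day 7 arrays lay in row 1 and all day 4 arrays in row 2, so the row of the slide goes with the day, while each normal group had 2 arrays in each row. No fit with slide or scan as a term was possible for them. Normal podocyte and glomerular arrays with the same number deviated together from their group means (correlation across genes 0.42 to 0.51 in the 4 pairs, 8 of 8 arrays closest to their own number). The pairing comes from these values and not from the labels, and such arrays also lay side by side on the slide. The other groups did not pair.

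Alternatives tried were quantile normalization, normexp background correction (offset 50) with either scaling, each array's median set to 0, no filter on dim probes, only probes above background on all 16 arrays, the mean of a gene's probes, the authors' value table, array weights, a trended robust variance, only the 8 arrays compared, the replicate number as a block, and leaving out each array. Normexp on the mean signal could not be run, since the files hold no mean signal, and was run on the median signal instead, an alternative chosen after seeing the data. The median set to 0 and the fit without the 2 LMB2 arrays richest in proximal tubule genes were also chosen after seeing the data.

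The model was tested on simulated data built from the arrays' own means and spreads over the 14573 genes. For podocyte against glomerular RNA it recovered 26% of the genes changed by a log2 difference of 0.5, 76% of those changed by 1, 96% by 2 and 100% by 4, and it called 3 of 14353 unchanged genes. For day 4 against normal the shares were 28%, 68%, 96% and 100%, with 9 unchanged genes called. For day 7 against normal they were 30%, 82%, 92% and 98%, with 12 unchanged genes called, and for day 7 against day 4 they were 26%, 80%, 88% and 100%, with 14. A list of 20 genes shifted by 0.5 was found by camera in all 4 comparisons, and 0 of 20 unchanged lists had p under 0.05 in each. The genes were simulated independently of each other, while the correlations estimated in the real lists ran from 0.064 to 0.83, highest in proximal tubule genes. These list results therefore cannot show how far the p-values at the preset correlation hold for lists of correlated genes. The bar first set for the simulated genes, nearly full recovery at a log2 difference of 2 in each comparison, was missed. It was replaced, after that result was seen, by unbiased estimates and nearly full recovery at 4.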

Results

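Messenger RNA on ribosomes was measured in 4 groups of 4 arrays: podocytes of uninjured mice, whole glomeruli of uninjured mice, and podocytes 4 and 7 days after the immunotoxin LMB2. Between 49.3% and 57.5% of the spots of an array were well above background. The share was highest in glomerular RNA (mean 56.3% ± 0.94, SD, n = 4) and close to 51% in the 3 podocyte groups (51.3% ± 2.05 normal, 51.3% ± 1.11 at day 4, 51.7% ± 1.51 at day 7, SD, n = 4). The first principal component over all genes tested held 60.5% of the variance and set glomerular RNA, with scores from -149 to -140, apart from podocyte RNA, with scores of 15.2 and above. The second held 22.9% and ordered the podocyte arrays from normal (scores of -93.5 to -73.1) through day 4 (-3.13 to 31.3) to day 7 (55.8 to 69.7).

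**Figure D1:**
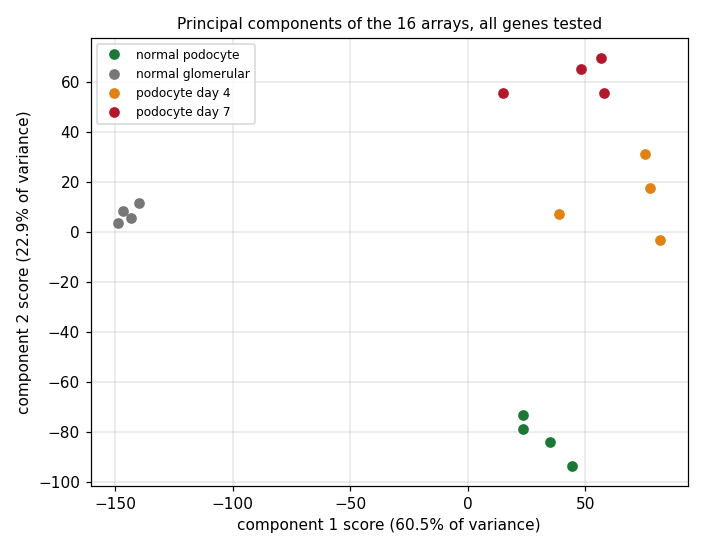
Scores of the 16 arrays on the first and second principal components of all genes tested, with the percentage of variance on each axis and 4 points per group. Glomerular arrays lie apart on the first component (60.5%), and the podocyte groups are ordered normal, day 4, day 7 on the second (22.9%).

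Podocyte polysome RNA was compared with glomerular polysome RNA of uninjured mice to ask which transcripts the tagged ribosomes held. Genes of the podocyte were higher: Wt1, a transcription factor of podocyte development and upkeep, was 4.92-fold higher (log2 2.30 ± 0.10, SE, n = 4 per group). Podxl, the main sialomucin of the podocyte surface, was 5.18-fold higher (log2 2.37 ± 0.12), and Nphs1, nephrin of the slit diaphragm, was higher by 2.32 ± 0.16. Dach1, a nuclear factor of podocytes, rose by a log2 difference of 2.66 ± 0.11. Robo2, a guidance receptor at the slit diaphragm, rose by 2.46 ± 0.12, and Synpo, an actin-binding protein of foot processes, by 1.54 ± 0.12. All 33 podocyte genes measured were called, 32 higher and 1 lower, with a median of 2.25 against 0.38 for all genes. The counts were the same adjusted over the list alone. In camera the list stood above other genes (adjusted p = 2.0e-08), and adjusted p = 0.29 with an estimated correlation. The gene that was lower was Trpc6, a calcium channel, at -2.40 ± 0.63.

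Transcripts of other kidney cells were lower in podocyte RNA. Of 22 endothelial markers 21 were lower and 1 higher, with a median of -4.34 (camera adjusted p = 1.7e-12, and adjusted p = 0.21 with an estimated correlation). Among them were Pecam1, an endothelial adhesion molecule, at -4.01 ± 0.15, Ramp2, a coreceptor for adrenomedullin, at -4.75 ± 0.21, and Sox18, a vascular transcription factor, at -4.67 ± 0.23. Emcn, the sialomucin endomucin, was 38.4-fold lower. The exception was Cldn5, a tight junction protein, at 2.76. Of 17 mesangial and smooth muscle markers 16 were lower, with a median of -3.49 (adjusted p = 1.2e-07, and adjusted p = 0.21 with an estimated correlation). They included Fhl2, a LIM domain cofactor, at -4.00 ± 0.22, Agtr1a, the angiotensin II receptor, at -4.23 ± 0.23, and Des, the intermediate filament desmin, at -2.64 ± 0.16, while Mylk, myosin light chain kinase, was higher at 1.47 ± 0.08. Of 8 parietal epithelial markers 5 were lower and 1 higher (median -1.68, adjusted p = 0.028; adjusted p = 0.34 with an estimated correlation). The lowest was Wfdc2, a secreted whey acidic protein, at -4.89 ± 0.33, with Krt18, a simple epithelial keratin, at -3.43 ± 0.42. The call of the parietal list was lost with quantile normalization, where its median was -1.53. After normexp correction the parietal median was -1.12 or -1.04, by the scaling, and the mesangial median -2.69 with both.

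Tubule and blood cell transcripts were lower as well. All 24 proximal tubule genes were lower (median -3.33, adjusted p = 3.1e-06; adjusted p = 0.41 with an estimated correlation). Examples are Aqp1, a water channel, at -4.24 ± 0.53, and Slc22a6, an organic anion transporter, at -4.60 ± 0.73. Of 15 distal nephron genes 13 were lower, 14 adjusted over the list alone (median -3.86, adjusted p = 1.5e-06; adjusted p = 0.21 with an estimated correlation). Pvalb, a calcium-binding protein of the distal tubule, was lower at -3.78 ± 0.28. Of 19 leukocyte genes 16 were lower (median -4.32, adjusted p = 1.5e-06; adjusted p = 0.29 with an estimated correlation). Among these were Cd74, the invariant chain of antigen presentation, at -4.64 ± 0.47, and Fcer1g, an immune receptor chain, at -3.77 ± 0.31. All 6 red blood cell genes were lower (median -4.15, adjusted p = 0.0015; adjusted p = 0.34 with an estimated correlation), with the globin gene Hba-a1 at -4.22 ± 0.56. After normexp correction with either scaling the medians shrank, to -2.46 and -2.36 for distal nephron, -2.29 and -2.19 for leukocyte and -3.56 and -3.65 for red blood cell genes. With genes known only as a bound set at their bound, they were -3.78 for distal nephron and -3.79 for leukocyte genes.

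**Figure D2:**
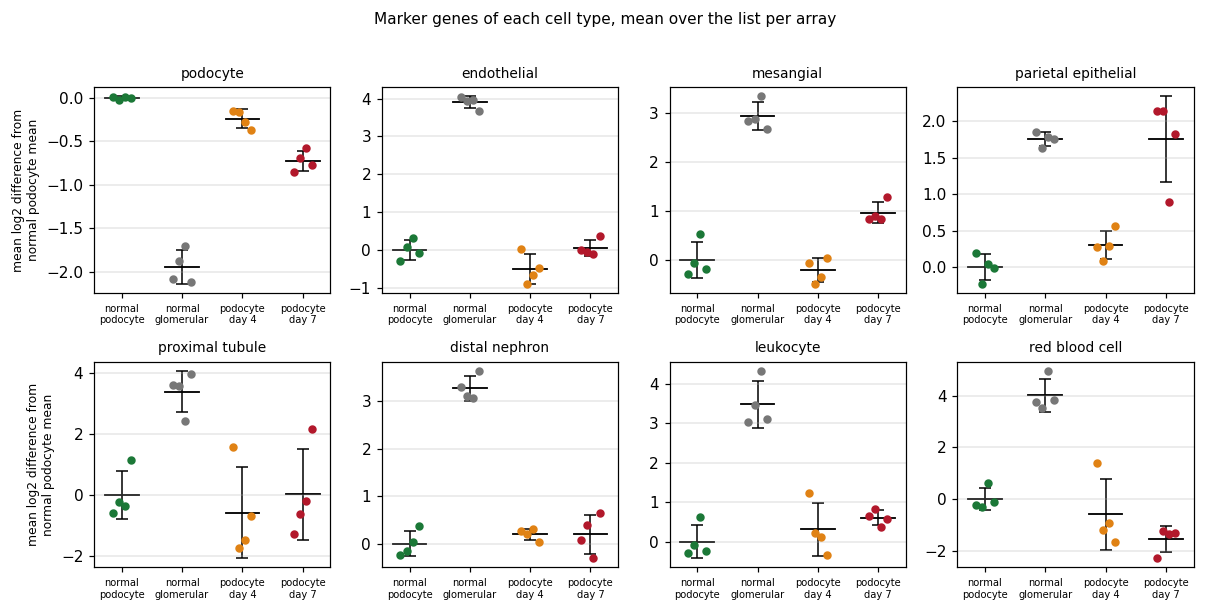
Mean log2 difference from the mean of normal podocytes over the marker genes of each cell type, with a point per array, the group mean as a line and the SD as an error bar (n = 4). The podocyte list was lowest in glomerular RNA (mean -1.94) and lower at day 7 (mean -0.72) than in normal podocytes, and the parietal list was higher at day 7 (mean 1.75).

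Other groups of genes also differed between the preparations. Genes of the glomerular basement membrane split by gene: Col4a3, Col4a4 and Col4a5, the chains of the mature collagen network, were higher (2.67 ± 0.20, 2.49 ± 0.15 and 2.37 ± 0.14). Nid1 (nidogen) and Hspg2 (perlecan), which other cells make too, were lower (-3.49 ± 0.15 and -3.30 ± 0.18). In all 10 of 14 were higher and 3 lower, with no call for the list (adjusted p = 0.17). Lists lower in podocyte RNA were cytokines and NF-kappaB targets (median -0.98, adjusted p = 0.0021; adjusted p = 0.34 with an estimated correlation), and injury-related matrix (median -1.98, adjusted p = 0.0013; adjusted p = 0.21 with an estimated correlation). So were interferon-stimulated genes, 12 of 18 lower and 2 higher (median -2.19, adjusted p = 3.6e-04; adjusted p = 0.34 with an estimated correlation), proliferation genes (median -1.79, adjusted p = 7.1e-04; adjusted p = 0.34 with an estimated correlation) and p53 targets (median -0.82, adjusted p = 0.047; adjusted p = 0.34 with an estimated correlation). After normexp correction with either scaling the median of proliferation genes was -0.54 or -0.61, of matrix genes -0.83 or -0.98 and of cytokines and NF-kappaB targets -0.50 or -0.46. With genes known only as a bound set at their bound, the medians were -0.64 for cytokines and NF-kappaB targets and -0.61 for p53 targets. Ribosomal protein genes were lower too, 52 of 78 called lower and 4 higher, or 50 and 4 adjusted over the list alone (median -0.47, adjusted p = 4.8e-08; adjusted p = 0.49 with an estimated correlation), and 69 were lower with quantile normalization. Rpl22, which carries the tag, was lower at -1.40 ± 0.13, but its second probe gave 1.49, and with the mean of both probes the direction turned (0.05, adjusted p = 0.74). Eef2 was not called (-0.11 ± 0.09, adjusted p = 0.31), but was called lower with quantile normalization (-0.29, adjusted p = 0.024) and after normexp correction with it (-0.26, adjusted p = 0.042).

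Among genes above background on all 8 arrays, clone identifiers apart, the largest rises were in Olfr629, an olfactory receptor gene (log2 3.61 ± 0.17), Tcf21, a transcription factor of the podocyte lineage (11.9-fold, log2 3.57 ± 0.18), and Sox8, a transcription factor (3.43 ± 0.41). Next came Sowahd, an ankyrin repeat protein (3.42 ± 0.16), Myoz1, a calcineurin-binding protein of muscle (3.40 ± 0.18), and Ube2ql1, a protein of the ubiquitin pathway (3.38 ± 0.22). The largest falls were in Srgn, the proteoglycan serglycin of blood and endothelial cells (40.3-fold, log2 -5.33 ± 0.28), Fxyd5, a regulator of the sodium pump (-5.32 ± 0.23), and Tyrobp, a signalling adaptor of myeloid cells (-5.31 ± 0.55). Close to these were Emcn (-5.26 ± 0.26), Ecscr, an endothelial surface protein (-5.23 ± 0.24), and Tmem213, a gene of the distal nephron list (-5.12 ± 0.45). Foxa2, a forkhead transcription factor, was at least 8.35-fold higher, Sntg2, a syntrophin, at least 6.01-fold, and Syna, an envelope-derived fusion protein, at least 5.09-fold. Sirpb1b, a receptor of myeloid cells, was at least 27.0-fold lower, Arhgap15, a Rac-inhibiting protein, at least 21.8-fold, and Art4, a blood group protein, at least 21.6-fold. Of 14573 genes tested with limma, 7514 were higher and 4019 lower in podocyte RNA, 2809 and 3154 of them at least 2-fold. The sum of these, 5963, was 4138 or 3439 after normexp correction with either scaling. The groups did not overlap for 73.0% of genes, against 2.86% by chance. The median over all genes of 0.38 moved to between 0.17 and 0.33 under 4 other scalings.

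Podocytes 4 days after LMB2 were compared with normal podocytes to describe the early response to the toxin. Among genes above background on all 8 arrays the largest rises were in 3 genes: Maff, a small bZIP transcription factor, was 875-fold higher (log2 9.77 ± 0.23, SE, n = 4 per group), P2rx7, an ATP-gated channel, 436-fold (log2 8.77 ± 0.20), and Cxcl1, a chemokine that draws neutrophils, 199-fold (log2 7.64 ± 0.45). The mean of the podocyte list was -0.24 ± 0.11 (SD, n = 4) against normal podocytes at this time, nearer to normal than at day 7 (-0.72). Nphs1 fell by 0.56 ± 0.16 (adjusted p = 0.012) and Podxl by 0.67 ± 0.12 (adjusted p = 9.5e-04), while Wt1 was not called (-0.17 ± 0.10, adjusted p = 0.21).

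Of 21 cytokine and NF-kappaB target genes 12 rose and none fell, with a median of 1.78 (camera adjusted p = 1.5e-12; adjusted p = 0.14 with an estimated correlation). Among them were Cxcl16, a membrane chemokine (5.67 ± 0.23), Cxcl10, an interferon-inducible chemokine (4.94 ± 0.30), and Nfkb2, a subunit of NF-kappaB (2.71 ± 0.20). After normexp correction with either scaling the median of these targets was smaller, 0.86 or 0.94. Of 19 immediate early genes 14 rose and none fell (median 1.56, adjusted p = 1.3e-09; adjusted p = 0.25 with an estimated correlation), and the median was 0.97 or 0.86 after normexp correction. Highest were the transcription factors Egr2 (6.18 ± 0.49) and Egr1 (6.13 ± 0.52), with Fosl1, an AP-1 subunit, at 3.08 ± 0.32 and Atf3, a stress-induced factor, at 2.87 ± 0.33. Of 19 p53 targets 10 rose and 4 fell (median 0.50, adjusted p = 0.0033; adjusted p = 0.25 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 4.36 ± 0.50, Tnfrsf10b, a death receptor, by 2.72 ± 0.19, and Phlda3, an inhibitor of Akt, by 2.51 ± 0.18, while Ei24, a protein of the endoplasmic reticulum, fell by 1.09 ± 0.11. The other probe of Cdkn1a gave 0.97. Of 18 proliferation genes 8 rose and 1 fell, 8 and 2 adjusted over the list alone (median 0.29, adjusted p = 0.0040; adjusted p = 0.84 with an estimated correlation). These were led by Birc5, survivin of the mitotic chromosomes (6.39 ± 0.34), Ccna2, cyclin A2 (4.34 ± 0.37), Ccnb2, cyclin B2 (2.94 ± 0.39), and Plk1, a mitotic kinase (2.42 ± 0.29), while Mki67, the usual proliferation marker, was not called (-0.68). After normexp correction the median of proliferation genes was 0.20 or 0.11 and that of p53 targets 0.40 or 0.30.

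Of 33 podocyte genes 9 fell and 1 rose, 8 and 1 adjusted over the list alone, with a median of -0.22 against -0.14 for all genes and no call for the list (adjusted p = 0.24). Members ran from -1.81 to 0.47. The list mean of every day 4 array (-0.37 to -0.15) lay below that of every normal podocyte array (-0.02 to 0.01). The falls numbered 7 with quantile normalization, 13 or 8 after normexp correction and 5 with each array's median set to 0, with medians from -0.20 to -0.13. Robo2 fell by 0.46 ± 0.12, a call lost with the mean of its probes (-0.30). Synpo fell by 0.41 ± 0.12 (adjusted p = 0.021), a call lost without replicate 3 (-0.32) or replicate 4 (-0.38) of day 4, with each array's median set to 0 (-0.32) and with the mean of its probes (-0.24). Of 78 ribosomal protein genes 5 rose and 1 fell, none adjusted over the list alone (median 0.08, adjusted p = 0.0056; adjusted p = 0.86 with an estimated correlation), and that call was lost after normexp correction with the 75th percentile. The rises numbered 19 with quantile normalization, 5 or 21 after normexp correction and 13 with each array's median set to 0. Rpl22 (-0.08 ± 0.13, adjusted p = 0.67) and Eef2 (-0.11 ± 0.09, adjusted p = 0.38) were not called. Of 16 YAP and TEAD targets 6 rose and 1 fell (median 0.13, adjusted p = 0.053), led by Ankrd1, a mechanically induced nuclear protein (2.62 ± 0.24), and Ccn1, a matricellular protein (2.44 ± 0.38). No marker list of another cell type was called at day 4. The endothelial list had a median of -0.52 (5 of 22 fell, adjusted p = 0.074), the proximal tubule list -0.59 (0 of 24 called, adjusted p = 0.93) and the leukocyte list 0.28 (3 of 19 rose, 1 adjusted over the list alone, adjusted p = 0.089). The mesangial list had a median of -0.35 and a mean of -0.21 (2 rose and 2 fell of 17), while camera ranked it up with adjusted p = 0.94. Replicate 1 of day 4 stood apart in proximal tubule genes, with a list mean of 1.55 above normal podocytes against a group mean of -0.57 ± 1.48 (SD, n = 4), or -1.28 without it. The leukocyte mean of 0.31 also came from that array (1.24), with the other 3 between -0.34 and 0.22. Normal podocyte replicate 4 was high in proximal tubule genes too, at 1.15 above the normal mean.

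**Figure D3:**
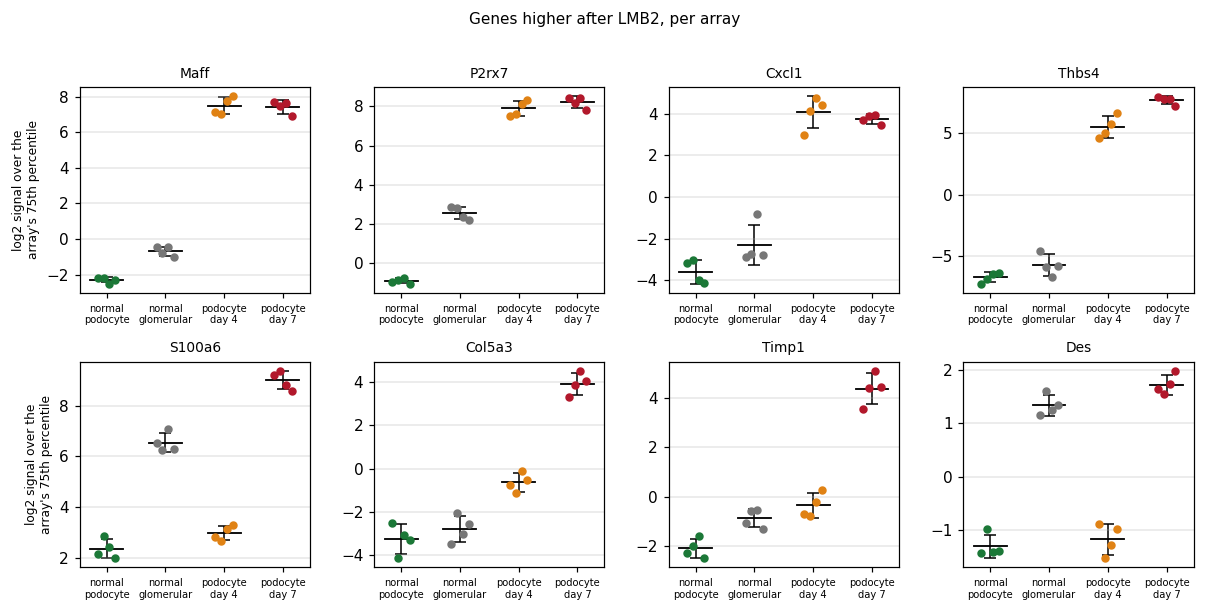
Log2 signal over the array's 75th percentile for 8 genes higher after LMB2, with a point per array, the group mean as a line and the SD as an error bar (n = 4). Maff, P2rx7, Cxcl1 and Thbs4 were already high at day 4, while S100a6, Col5a3, Timp1 and Des were highest at day 7, where S100a6 had a mean of 9.01 against 2.97 at day 4.

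The other large rises at day 4 were in Prr7, a proline-rich membrane protein (7.32 ± 0.27), Zmynd15, a zinc finger protein of germ cells (7.03 ± 0.39), and Gem, a small GTPase of the RGK family (6.69 ± 0.32). The largest falls among genes above background on all 8 arrays were in Hoxd9, a homeobox gene (-2.17 ± 0.23), Tfrc, the transferrin receptor (-2.17 ± 0.18), and Cyp26a1, which degrades retinoic acid (-1.94 ± 0.57). Then came Dusp26, a phosphatase (-1.79 ± 0.49), Psap, the precursor of lysosomal saposins (-1.79 ± 0.19), and Wfdc1, a secreted protease inhibitor (-1.75 ± 0.52). The call of Cyp26a1 was lost without replicate 4 of day 4 (adjusted p = 0.061), and that of Wfdc1 without replicate 1 of day 4 (-1.55) or normal replicate 2 (-1.23). With the replicate number as a block in the 8 arrays compared, the calls of Dusp26 (adjusted p = 0.0503) and Wfdc1 (adjusted p = 0.064) were lost. Epha8, an ephrin receptor, was at least 1865-fold higher, Thbs4, a thrombospondin, at least 1112-fold, and Tmprss9, a serine protease, at least 804-fold, each above background on no normal podocyte array. Cenpa, the centromeric histone, was at least 2.47-fold lower, Sfmbt2, a Polycomb protein, at least 1.92-fold and Stac, an adaptor of calcium channels, at least 1.88-fold, and the calls of these 3 were lost after normexp correction with the 75th percentile (-0.21, -0.12 and -0.16) and kept, at smaller values, with quantile normalization after it (-0.43, -0.34 and -0.38).

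By limma 1759 genes were higher and 3155 lower at day 4, 998 and 211 of them at least 2-fold. The sum of these, 1209, was 560 or 508 after normexp correction with either scaling. The groups did not overlap for 34.1% of genes, against 2.86% by chance. The median of all genes lay at -0.14, and with each array's median set to 0 the calls were 2026 higher and 2086 lower, so the count of small falls moved with the scaling. Normal and LMB2 arrays lay on different slides and came from different genotypes, so slide, genotype and toxin cannot be told apart here.

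Podocytes 7 days after LMB2 were compared with normal podocytes to describe the later response. Genes of podocyte identity were lower: Nphs1 fell by 1.45 ± 0.16 (2.73-fold), Podxl by 1.35 ± 0.12 (2.55-fold) and Wt1 by 0.98 ± 0.10 (1.98-fold). Sema3g, a secreted semaphorin of podocytes, fell by 3.34 ± 0.26 (10.1-fold, SE, n = 4 per group). Of 33 podocyte genes 20 fell and 1 rose, 20 and 2 adjusted over the list alone, with a median of -0.78 against -0.14 for all genes (camera adjusted p = 0.0011; adjusted p = 0.59 with an estimated correlation). With each array's median set to 0, 20 fell and 5 rose. The list mean was -0.72 ± 0.12 (SD, n = 4) at day 7 and lay below all normal podocyte arrays in 4 of 4. Synpo fell by 1.03 ± 0.12, although its second probe gave 0.29. The riser was Actn4, an actin crosslinker, at 0.88.

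Inflammatory, mechanical and matrix genes were higher. Of 21 cytokine and NF-kappaB targets 19 rose and none fell (median 3.10, adjusted p = 2.2e-13; adjusted p = 0.11 with an estimated correlation). Among them were Cxcl10 (6.74 ± 0.30), Csf1, the macrophage growth factor (4.34 ± 0.20), Cxcl16 (4.44 ± 0.23), and Saa3, an acute phase protein, at least 19.1-fold higher. The median was 2.42 or 2.43 after normexp correction, and 2.80 with genes known only as a bound set at their bound. Of 19 injury-related matrix genes 13 rose and 1 fell (median 2.30-fold, mean 1.68, adjusted p = 3.9e-05; adjusted p = 0.11 with an estimated correlation), and the median was 0.97 or 0.96 after normexp correction. They included Timp1, an inhibitor of metalloproteinases (6.48 ± 0.32), and Tgfb1, a fibrogenic cytokine (1.81 ± 0.12). Of 16 YAP and TEAD targets 11 rose and 2 fell, 11 and 3 adjusted over the list alone (median 1.11, adjusted p = 3.3e-04; adjusted p = 0.15 with an estimated correlation). Ankrd1 stood at 5.24 ± 0.24 and the growth factor Tgfb2 at 4.77 ± 0.29. Of 21 actin and adhesion genes 14 rose and 1 fell (median 0.68, adjusted p = 9.9e-05; adjusted p = 0.19 with an estimated correlation). The crosslinker Actn1 stood at 2.96 ± 0.13 and the focal adhesion protein Zyx at 2.22 ± 0.13. Tpm1, a tropomyosin of that list, rose by 1.65 ± 0.16, but its probes ran from -0.16 to 3.18.

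Immediate early genes, p53 targets and proliferation genes were called as lists at day 7 too. Of 19 immediate early genes 16 rose and none fell, 18 and 1 adjusted over the list alone (median 1.86, adjusted p = 4.6e-08; adjusted p = 0.19 with an estimated correlation). Egr1 stood at 6.39 ± 0.52, Fosl1 at 4.65 ± 0.32 and Myc, a growth-promoting transcription factor, at 4.42 ± 0.38. Of 19 p53 targets 12 rose and 4 fell (median 0.69, adjusted p = 0.0093; adjusted p = 0.19 with an estimated correlation), with Plk2, a polo-like kinase, at 4.40 ± 0.36 and Tnfrsf10b at 2.98 ± 0.19. Of 18 proliferation genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone (median 1.19, adjusted p = 8.0e-05; adjusted p = 0.29 with an estimated correlation), with Birc5 at 5.14 ± 0.34 and Plk1 at 3.82 ± 0.29. The median of proliferation genes was 0.73 or 0.70 after normexp correction. Of 78 ribosomal protein genes 25 rose and 1 fell, 19 and 1 adjusted over the list alone (median 0.25, adjusted p = 1.2e-04; adjusted p = 0.73 with an estimated correlation), and the rises ran from 23 to 44 under 4 other scalings. Rpl22 was not called (0.18 ± 0.13, adjusted p = 0.24). It was called higher with quantile normalization (0.35), and with the mean of its probes the direction turned (-0.42, adjusted p = 0.013). Eef2 was not called (-0.02 ± 0.09, adjusted p = 0.86).

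**Figure D4:**
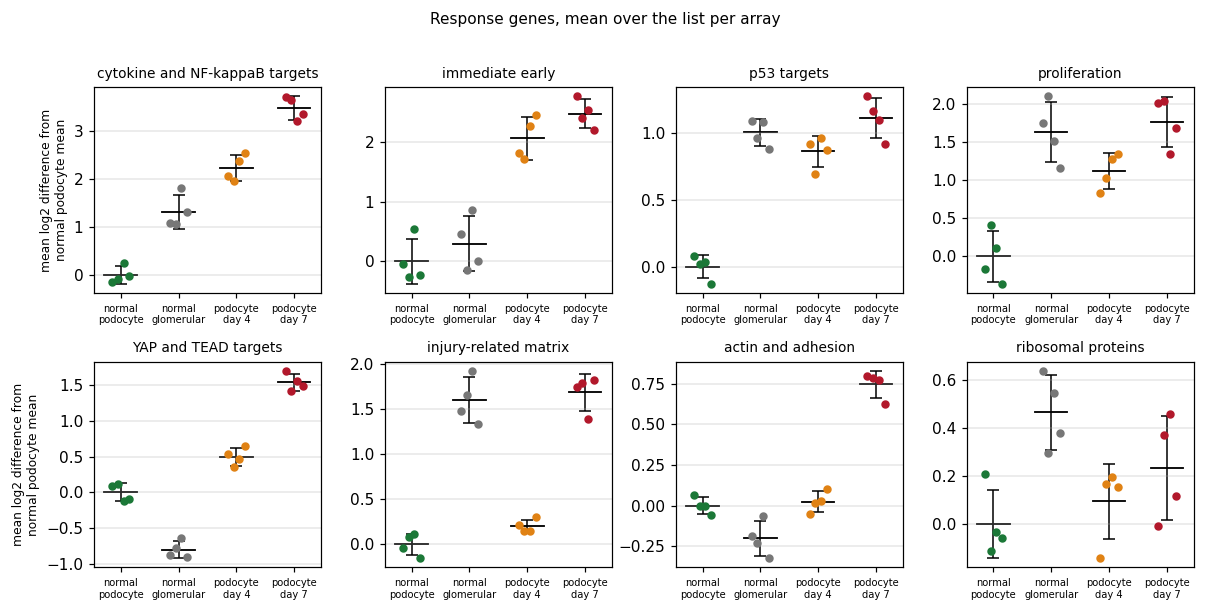
Mean log2 difference from the mean of normal podocytes over 8 lists of response genes, with a point per array, the group mean as a line and the SD as an error bar (n = 4). Cytokine and immediate early genes were already high at day 4 (means 2.24 and 2.06), while matrix genes were high at day 7 (1.68) and not at day 4 (0.20).

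Markers of other glomerular cells moved apart from each other at day 7. All 8 parietal epithelial genes rose (median 1.88, adjusted p = 0.0011; adjusted p = 0.19 with an estimated correlation). They included Cd44, a hyaluronan receptor of activated parietal cells (2.33 ± 0.33), Cldn1, a tight junction protein (2.21 ± 0.36), Scin, an actin-severing protein (2.72 ± 0.48), and Krt18 (2.14 ± 0.42). After normexp correction the parietal median was 1.14 or 1.08. Of 17 mesangial and smooth muscle genes 7 rose and none fell (median 0.46, adjusted p = 0.0093; adjusted p = 0.58 with an estimated correlation). Highest was the smooth muscle protein Tagln at 6.01 ± 0.25, then Des at 3.02 ± 0.16 and Acta2, smooth muscle actin, at 1.60 ± 0.32. The endothelial list was not called (median 0.19, 4 rose and 3 fell of 22, 1 and 3 adjusted over the list alone, adjusted p = 0.40). Nor were the proximal tubule (median 0.00, 1 of 24 rose, adjusted p = 0.40), distal nephron (median 0.00, adjusted p = 0.40), leukocyte (median 0.30, adjusted p = 0.099) and red blood cell lists (median -1.59, 5 of 6 fell, adjusted p = 0.24), the last with a median of -0.64 or -0.80 after normexp correction. Replicate 4 of day 7 stood apart in proximal tubule genes, with a list mean of 2.16 above normal podocytes. The other 3 day 7 arrays all lay below the normal mean (-1.28 to -0.19), so the group mean of 0.02 rests on replicate 4 of day 7. The normal mean rests in part on 1 array too: normal podocyte replicate 4 lay at 1.15, and normal replicates 1 to 3 at -0.58, -0.22 and -0.35. Of 14 basement membrane genes 4 rose and 5 fell, with Lamb2, a laminin chain of the mature membrane, at -1.34 ± 0.13 and Nid1 at 1.02 ± 0.15 (list adjusted p = 0.40).

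**Figure D5:**
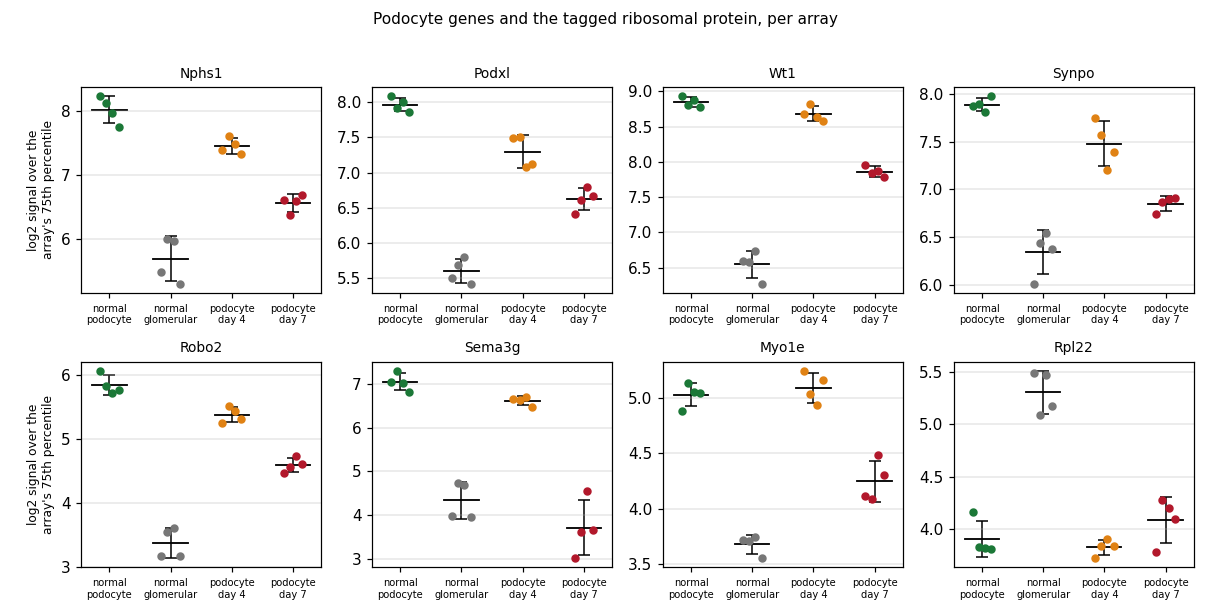
Log2 signal over the array's 75th percentile for 7 podocyte genes and Rpl22, with a point per array, the group mean as a line and the SD as an error bar (n = 4). Nphs1, Podxl, Wt1, Synpo, Robo2, Sema3g and Myo1e were lower at day 7 than in normal podocytes, with means of 7.86 at day 7 and 8.85 in normal podocytes for Wt1.

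Among genes above background on all 8 arrays, the largest rises at day 7 were in Maff (844-fold, log2 9.72 ± 0.23), P2rx7 (543-fold, 9.08 ± 0.20), Cxcl1 (7.32 ± 0.45), Zmynd15 (7.18 ± 0.39), Gem (7.16 ± 0.32) and Col5a3, a fibrillar collagen chain (7.16 ± 0.37). The largest falls were in Cyp26a1 (21.6-fold, log2 -4.43 ± 0.57) and Adra2c, an adrenergic receptor (-3.87 ± 0.27), followed by Pld6, a mitochondrial phospholipase (-3.42 ± 0.30), Sema3g, Sla, an adaptor of immune receptors (-3.18 ± 0.27), and Kcna6, a potassium channel (-3.07 ± 0.52). Thbs4 was at least 4957-fold higher, Epha8 at least 802-fold and Crct1, a cornified epithelium protein, at least 716-fold. Spata21, a calcium-binding protein of the testis, was at least 8.63-fold lower, Opcml, a GPI-anchored adhesion protein, at least 4.97-fold and Sntg2 at least 4.34-fold. By limma 3204 genes were higher and 5296 lower, 1753 and 1079 of them at least 2-fold. The sum of these, 2832, was 1634 or 1374 after normexp correction with either scaling. The groups did not overlap for 50.6% of genes, against 2.86% by chance. The median over all genes was -0.14 and moved to between -0.13 and -0.03 under 4 other scalings. As at day 4, slide and genotype differ with the toxin and cannot be told apart from it.

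Day 7 was compared directly with day 4 to follow the course of injury, with all 8 arrays on 1 slide, day 7 in row 1 and day 4 in row 2. S100a6, a calcium-binding protein of injured epithelium, was 65.6-fold higher at day 7 (log2 6.04 ± 0.23, SE, n = 4 per group) and Timp1 26.8-fold (4.74 ± 0.32), while Sema3g was 7.53-fold lower (-2.91 ± 0.26). Several podocyte genes fell from day 4 to day 7: Nphs1 by 0.88 ± 0.16, Wt1 by 0.82 ± 0.10, Podxl by 0.68 ± 0.12, Synpo by 0.62 ± 0.12 (its second probe gave 0.37, and the call was lost with the mean of its probes, -0.13), and Myo1e, a myosin of foot processes, by 0.85 ± 0.10. Of 33 podocyte genes 19 fell and 2 rose (median -0.56, adjusted p = 3.7e-05; adjusted p = 0.52 with an estimated correlation).

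Of 19 matrix genes 13 rose and 1 fell (median 1.22, adjusted p = 1.8e-06; adjusted p = 0.089 with an estimated correlation). The collagen chain Col1a1 was higher at 2.90 ± 0.31 and Tgfb1 at 1.86 ± 0.12. Of 21 actin and adhesion genes 12 rose and 1 fell (median 0.60, adjusted p = 8.4e-07; adjusted p = 0.095 with an estimated correlation), with Actn1 at 1.93 ± 0.13, Zyx at 1.85 ± 0.13 and Tpm4, a tropomyosin, at 1.84 ± 0.13. Of 16 YAP and TEAD targets 9 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.89, adjusted p = 3.7e-05; adjusted p = 0.095 with an estimated correlation), with Tgfb2 at 3.24 ± 0.29 and Ccn2, connective tissue growth factor, at 2.19 ± 0.33. Of 21 cytokine and NF-kappaB targets 11 rose and 1 fell (median 1.101, adjusted p = 8.2e-06; adjusted p = 0.24 with an estimated correlation), and the median was 0.66 or 0.67 after normexp correction. Ccl2, the chemokine that draws monocytes, was at least 20.1-fold higher, Ccl7, a related chemokine, at least 5.68-fold and Csf1 rose by 2.56 ± 0.20, while Cxcl16 was the member that fell, at -1.23. Immediate early genes rose in 8 of 19 and fell in 1, 9 and 1 adjusted over the list alone (median 0.52, adjusted p = 0.013; adjusted p = 0.68 with an estimated correlation). Proliferation genes rose in 6 of 18 and fell in 1 (median 0.52, adjusted p = 0.0052; adjusted p = 0.55 with an estimated correlation), with Mki67 at 2.42 ± 0.49 and Birc5 at -1.24 ± 0.34. The median of proliferation genes from day 4 to day 7 was 0.31 or 0.33 after normexp correction. The p53 list did not differ detectably (median 0.19, 4 rose and 2 fell of 19, adjusted p = 0.61).

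Mesangial and smooth muscle genes rose in 7 of 17, 8 adjusted over the list alone (median 0.73, adjusted p = 3.7e-05; adjusted p = 0.27 with an estimated correlation), with Tagln at 4.43 ± 0.25, Des at 2.89 ± 0.16 and Acta2 at 1.69 ± 0.32. Parietal epithelial genes rose in 6 of 8, 8 adjusted over the list alone (median 1.43, adjusted p = 2.7e-04; adjusted p = 0.18 with an estimated correlation), with Krt18 at 2.45 ± 0.42 and Cd44 at 1.81 ± 0.33. Endothelial genes rose in 8 of 22 and fell in 2, 13 and 2 adjusted over the list alone (median 0.64, adjusted p = 7.2e-04; adjusted p = 0.55 with an estimated correlation), with Pecam1 at 0.71 ± 0.15 and Esam, an endothelial adhesion molecule, at 1.19 ± 0.28. The endothelial median was 0.42 or 0.41 after normexp correction. Ribosomal protein genes were called as a list (median 0.12, adjusted p = 0.0042; adjusted p = 0.82 with an estimated correlation) with 2 of 78 higher and 1 lower, none adjusted over the list alone, and that call was lost with quantile normalization (0.04). Rpl22 was not called (0.26 ± 0.13, adjusted p = 0.13), but was without replicate 1 of day 7 (0.37, adjusted p = 0.038) and with quantile normalization (0.30). Eef2 was not called (0.09 ± 0.09, adjusted p = 0.49).

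The other large rises from day 4 to day 7 were in Col5a3 (4.55 ± 0.37), Tubb6, a beta-tubulin (4.48 ± 0.35), and Crygn, a crystallin (4.47 ± 0.29). Nppa, atrial natriuretic peptide, was at least 34.8-fold and Obox6, an oocyte homeobox gene, at least 6.22-fold higher. The largest falls among genes above background on all 8 arrays were in Dner, a Notch-related transmembrane protein (-3.42 ± 0.26), Tmem179, a membrane protein (-3.28 ± 0.76), Psors1c2, a skin-expressed gene (-3.14 ± 0.65), Sema3g (-2.91 ± 0.26), Lrrc4, a synaptic adhesion protein (-2.89 ± 0.33), and Kcna6 (-2.81 ± 0.52). Chrm2, a muscarinic receptor, was at least 5.52-fold lower, Opcml at least 5.42-fold and Gipr, an incretin receptor, at least 4.27-fold. By limma 2045 genes were higher and 2711 lower at day 7, 931 and 356 of them at least 2-fold. The sum of these, 1287, was 600 or 624 after normexp correction with either scaling. The groups did not overlap for 33.1% of genes, against 2.86% by chance. The median of all genes was -0.04.

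Whether transcripts enriched in podocyte RNA moved after LMB2 was asked with normal arrays divided between the choice of genes and the measurement. Between 2450 and 3237 genes at least 2-fold higher in podocyte RNA were taken in each of 6 divisions. Their median change was -0.23 ± 0.08 at day 4 (SD over 4 arrays), against -0.14 for all genes, and -0.53 ± 0.05 at day 7, against -0.14 for all genes. At day 7, 80.4% of these genes lay below normal, compared with 57.7% of all genes, and at day 4, 74.0% against 63.2%. For genes at least 4-fold higher in podocyte RNA the median at day 7 was -0.86.

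The responses at day 4 and day 7 were compared to ask how far they overlap. Genes called the same way at both times numbered 4204, of which 1514 were higher and 2690 lower, and 60 were called in opposite directions. Independent lists of the same sizes would share 387 higher and 1147 lower genes. Unchanged groups, simulated as independent noise around the normal podocyte means with the normal group redrawn too, shared 0 called genes in 20 simulations. No gene differed in these simulations, so few could be called at all, and the 0 does not bear on the size of the overlap. With the normal arrays divided between the times, 1180.5 genes were higher on average in both (1145 to 1241 over 6 divisions) and 1637 lower in both (1187 to 2200). Across genes, which are not independent replicates, the changes at both times had a correlation of 0.83 and a covariance of 0.931, where the simulated values were 0.50 and 0.034, a difference in covariance of 0.897. Of 1209 genes called at least 2-fold changed at day 4, 1103 were called the same way at day 7. Both LMB2 groups shared a slide, a scan and a genotype that the normal arrays did not. A difference of slide or genotype could therefore give shared calls and covariance too, and dividing the normal arrays does not remove it.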

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

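The tests of other cells, of the slide and of its rows for the podocyte fall, and of glomerular RNA for the proximal tubule genes, were chosen after the result was seen, as was the margin of 1 SE required of the shares of genes detected only after LMB2.

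Called genes well above background on all day 7 arrays, with none of their probes so on any normal podocyte array, numbered 304. At day 4, 204 genes behaved so, 175 of them the same. Clone identifiers apart, these genes also had to rise at least 2-fold with groups that did not overlap. Whether their rise came from single probes is not settled. Of 50 with another probe, 62% ± 6.86 (SE, taking genes as independent) rose at least 2-fold by those probes, compared with 10.6% of 4561 genes. The 4561 were not required to be dim in normal podocytes, so these shares do not compare like with like. The bound of 50% was passed by under 2 SE, and the rest of the 304 had no other probe. RNA of other normal glomerular cells is argued against for most, since only 21.4% were above background on all 4 glomerular arrays and 60.5% on none. Between day 7 and day 4, on 1 slide but in different rows, 51.6% ± 2.87 (SE) differed, 139 higher and 18 lower, too near the bound of 50% to exclude the slide. Slide, genotype and toxin therefore cannot be told apart for the rise that both times share.

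Podocyte genes were lower at day 7 than in normal podocytes by a mean of -0.72. A larger share of RNA from other cells would raise the markers of each other type, but at day 7 endothelial genes had a mean of 0.05 ± 0.22 (SD, n = 4), mesangial genes 0.96 ± 0.21 and red blood cell genes -1.54 ± 0.49, the last an uncalled list of 6 whose median of -1.59 shrank to -0.64 (2 fell) and -0.80 (1 fell) after normexp correction. A gain of parietal or of mesangial cells, whose lists rose, stays open. A difference between slides as the whole cause is argued against by the fall of -0.48 between day 4 and day 7 on 1 slide. The choice among scalings that level the arrays on most genes is argued against by a list median of -0.61 or lower under 4 other such scalings. Scaling on the spike-in probes was not tried, so a change common to most genes was not tested. The part shared with day 4 keeps the slide and the genotype open.

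From day 4 to day 7 the fall of podocyte genes went with mean rises of 0.55 for endothelial, 1.17 for mesangial and 1.45 for parietal genes. The widest gap between these rises, 0.90, lay within 2 SD of the arrays, so a larger share of RNA from other cells, endothelial cells among them, stays open for this part. All day 7 arrays lay in row 1 of the slide and all day 4 arrays in row 2. A row effect common to both slides is argued against by a difference of -0.0155 between the rows in normal podocytes, 2 arrays each, while one on the LMB2 slide alone cannot be told apart from the day.

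Proximal tubule genes were high in replicate 1 of day 4 and replicate 4 of day 7, 2 arrays picked because that list was high. In the day 7 array they stood 2.86 above the other day 7 arrays and endothelial genes 0.42, which argues against carried-over glomerular RNA as the whole source, since in normal glomerular RNA these lists stand 3.38 and 3.90 above podocytes. All 24 proximal tubule genes were highest there, which restates how the array was picked, so RNA of proximal tubule cells stays open and untested. In the day 4 array the excess was 2.84, with 2.65 for red blood cell, 1.24 for leukocyte and 0.71 for endothelial genes. High proximal tubule genes were not confined to LMB2 arrays: normal podocyte replicate 4 lay 1.15 above the normal mean. Across all genes, its deviation from its group mean had a correlation of 0.45 with that of the day 4 array. With that of the day 7 array the correlation was 0.49. No biological explanation was tested, since the labels give no difference between these arrays and the others.

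Single arrays lay far from the other 3 of their group in 12 of 292 groups tested (4.11%, where chance gives about 5%). They were Rpl22 in normal podocyte replicate 1 (4.17), Srgn in normal podocyte replicate 2 (1.44), Tcf21 (2.21) and Cxcl1 (-0.84) in glomerular replicate 3, and the spike-in median in glomerular replicate 1 (804). At day 4 replicate 1 was apart in Emcn (0.59), Hoxd9 (-1.91) and the ribosomal protein list (-0.14). At day 7 replicate 4 was apart in the mesangial (1.28) and actin lists (0.62), replicate 1 in the red blood cell list (-2.27) and replicate 3 in the matrix list (1.38).

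The change from normal differed between day 7 and day 4 for 4756 genes. Day 7 minus day 4 was -0.88 for Nphs1, -0.68 for Podxl, -0.82 for Wt1 and -0.62 for Synpo, and the list medians were -0.56 for podocyte, 0.64 for endothelial, 0.73 for mesangial, 1.43 for parietal and 0.52 for immediate early genes. They were 0.89 for YAP and TEAD targets, 1.101 for cytokines and NF-kappaB targets, 1.22 for matrix, 0.52 for proliferation, 0.60 for actin and 0.12 for ribosomal protein genes. The lists are those called by camera, and each of these calls was lost with an estimated correlation.

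Outside the main measurement, 10 spike-in probes were brighter on LMB2 arrays by a mean log2 difference of 1.24 (0.03 to 1.69). This shift goes with slide, scan, genotype and toxin at once, and its cause was not tested. None of the scalings tried used the spike-in probes. Of 10644 probes without a gene name, 886 were at least 2-fold higher at day 4 and 1223 at day 7 than in normal podocytes.

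Other splits of the 8 arrays of a comparison tested whether chance gives as many calls. The real split called 4260 genes at day 4 against normal (highest other split 1), 7686 at day 7 against normal (highest other 0) and 4297 at day 7 against day 4 (highest other 0). Each was 1 of 35 splits, a share under 0.05 but the smallest that 35 splits can give. Chance is therefore argued against and not excluded. These comparisons share arrays, and the labels do not say whether each array holds a separate animal. For podocyte against glomerular RNA, where the arrays pair, the real split called 11366 genes and the highest other of the 8 that part each pair 0, and 8 splits are too few for a share under 0.05. Splits that leave a pair together called at most 1 gene. The real splits of day 4 and day 7 against normal are also the splits by slide, and that of day 7 against day 4 is the split by row of the slide.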

How the results depend on the processing

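The alternatives chosen after the data were seen were normexp on the median signal with either scaling, each array's median set to 0 and the fit without the 2 LMB2 arrays richest in proximal tubule genes. The values of named genes under all alternatives numbered 8978, of which 8688 kept direction and side of the threshold, 279 lost the call, 8 gained it and 3 turned direction. The list values numbered 437, of which 382 kept both, 44 lost the call, 11 gained it and none turned. Most named genes were picked for large changes or small adjusted p in these same data, and each recurs under many settings. The share of named gene values kept is therefore no measure for called genes in general.

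After normexp correction with the 75th percentile, the counts of genes changed at least 2-fold were 560 at day 4 against normal, 1634 at day 7 against normal and 600 at day 7 against day 4, and with quantile normalization 3439 for podocyte against glomerular RNA, 508, 1374 and 624. With probes above background on all 16 arrays, 2574 genes were lower in podocyte than in glomerular RNA, and 605 changed at least 2-fold at day 4 and 830 from day 4 to day 7, where fewer genes were tested. With each array's median set to 0, 2086 genes were lower at day 4. With the replicate number as a block in the 8 arrays compared, which leaves fewer degrees of freedom, 2441 genes were called at day 4 (1199 lower) and 2686 from day 4 to day 7 (1323 higher and 1363 lower). Under that block 55 of 416 named gene values lost the call, among them Dusp26, Wfdc1, Robo2 and Synpo at day 4 and Podxl from day 4 to day 7. For the other settings the cause was not tested.

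With the correlation estimated by camera, 0 lists were called in each of the 4 comparisons, against 14, 5, 11 and 11 at the preset correlation. With the mean of its probes Rpl22 turned to 0.049 in podocyte against glomerular RNA and to -0.42 at day 7, and Tpm1 to 1.22 at day 4 from -0.59, since the probes of each gene went opposite ways. The median of podocyte-enriched genes at day 7 was -0.86 for genes at least 4-fold enriched, and 1018 genes changed at least 2-fold in the same direction at both times.

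Without each array in turn, the calls ran from 11171 to 11350 for podocyte against glomerular RNA, 3790 to 4846 at day 4, 7809 to 8287 at day 7 and 3624 to 4401 from day 4 to day 7. The medians of podocyte-enriched genes ran from -0.28 to -0.21 at day 4 and from -0.56 to -0.52 at day 7. Without the 2 arrays richest in proximal tubule genes, 4474, 8253 and 3832 genes were called at day 4, at day 7 and between them, 4075, 7865 and 3580 of them called the same way with all arrays. Fits with slide or scan as a term, and normexp on the mean signal, were not run. Between 49.3% and 57.5% of spots stood well above background on an array, which limits the falls that could be measured in dim genes.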

Other observations

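No test in this part was added after its result was seen, but the gene names in the paragraph on courses were chosen after their values were seen.

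Genes of the unfolded protein and integrated stress responses split at day 7. Asns, which makes asparagine, rose by 2.90 ± 0.26 (SE, n = 4 per group), Ppp1r15a, a phosphatase subunit of the stress response, by 2.11 ± 0.22, Trib3, a pseudokinase, by 1.86 ± 0.43 and Chac1, which degrades glutathione, by 4.15 ± 0.42, while Pdia4, a disulfide isomerase of the endoplasmic reticulum, fell by 2.18 ± 0.20 and Edem1, which targets misfolded proteins, by 1.12 ± 0.10. In all 5 of 20 rose and 13 fell, with no call for the list (adjusted p = 0.37). The list was not called in the other comparisons either, with adjusted p = 0.073 for podocyte against glomerular RNA, 0.65 at day 4 and 0.29 for day 7 against day 4.

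Lists not called at day 7 against normal were lysosome and autophagy (2 rose and 14 fell of 20, 10 with each array's median set to 0, median -0.41, adjusted p = 0.088), oxidative phosphorylation (2 rose and 27 fell of 74, 2 and 23 adjusted over the list alone, median -0.26, adjusted p = 0.083), translation elongation (2 rose and 7 fell of 15, adjusted p = 0.29), cell death (6 rose and 5 fell of 20, adjusted p = 0.40) and interferon-stimulated genes (4 rose and 2 fell of 18, 3 and 2 adjusted over the list alone, adjusted p = 0.088). Over all genes 5296 of 14573 were lower at day 7, a share close to that of the oxidative phosphorylation genes. The falls in oxidative phosphorylation depended on the scaling: 38 with quantile normalization, 44 or 42 after normexp correction, and 16 with each array's median set to 0 (median -0.15). At day 4 these lists were not called either: adjusted p was 0.23, 0.11, 0.35, 0.47 and 0.35 in the same order. Nor were they for day 7 against day 4, with 0.29, 0.66, 0.66, 0.065 and 0.078.

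At day 4 the parietal (median 0.26, adjusted p = 0.28), distal nephron (-0.04, 0.28), red blood cell (-0.55, 0.66), basement membrane (-0.28, 0.39), matrix (0.21, 0.13) and actin (-0.13, 0.49) lists were not called. From day 4 to day 7 the proximal tubule (0.65, 0.14), distal nephron (0.00, 0.78), leukocyte (0.16, 0.61), red blood cell (-1.11, 0.27) and basement membrane (0.16, 0.14) lists were not called. Single arrays set some of these: the proximal tubule mean of 0.59 was -0.12 without replicate 4 of day 7 and 1.30 without replicate 1 of day 4. Without the latter array the red blood cell mean went from -0.95 to -0.29 from day 4 to day 7, and from -0.59 to -1.25 at day 4 against normal. The same array was highest in leukocyte genes at day 4 (1.24 against a group mean of 0.31), which lowered the leukocyte change from day 4 to day 7. Between podocyte and glomerular RNA immediate early (-0.63, 0.25), YAP and TEAD (1.42, 0.16), actin (0.35, 0.48), cell death (-0.55, 0.064), lysosome (0.63, 0.13), elongation (0.51, 0.26) and oxidative phosphorylation genes (0.32, 0.13) were not called. After normexp correction with either scaling the red blood cell medians were -0.20 or -0.27 at day 4 and -0.47 or -0.55 from day 4 to day 7, and the immediate early median was -0.14 or -0.12. With quantile normalization the oxidative phosphorylation median was 0.06.

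Of 998 genes at least 2-fold higher at day 4, 132 were lower at day 7 than at day 4, 276 higher and 590 not called between them. Above background on no normal podocyte array, Dner was at least 40.1-fold higher at day 4 and at least 3.76-fold at day 7, and Ptprn, a protein of secretory granules, at least 21.0-fold and 3.67-fold. Of 1753 genes at least 2-fold higher at day 7, 536 were not called at day 4 and were higher than at day 4, and of 1079 at least 2-fold lower, 290 were not called at day 4 and were lower than at day 4.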
